A study of Mus musculus with 14 samples.

How the data were processed

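Total RNA from a piece of the left liver lobe of 14 mice was sequenced, with 1 library per animal. The labels place 4 libraries in a control group (floxed Tet2 without cre), 5 in an asymptomatic group (floxed Tet2 with Vav-cre) and 5 in a group with spontaneous autoimmune hepatitis (AIH; floxed Tet2 with Vav-cre). All mice were 20 weeks old. Replicate numbers follow accession order only and pair no animals. Library numbers ran from 11 to 15 in AIH and from 1 to 10 in the other groups. If they give the order of preparation, that order cannot be told apart from AIH.

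The deposited files hold raw counts per Ensembl gene, not normalized. Per the submitters' processing notes, the tools named are FastQC 0.11.5, cutadapt 1.12, HISAT2 2.1.0, HTSeq 0.9.0, edgeR and R 4.0, with no roles or order. The notes name a human and a mouse build. The gene IDs are mouse, so GRCm38 was used for positions. The annotation release, the strand setting and the sequencing layout were not given in the sources used here. Without a stated strand setting, reads from overlapping and antisense genes cannot be told apart. Genes with near-identical copies, among them the Cyp3a, Ugt, Sult2a, Orm and immunoglobulin genes, may have lost or shared reads.

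Each file lists 51912 gene rows and 5 HTSeq summary rows. The summary rows name no gene and stayed out of library sizes and tests. Of all reads in a file, 3.23% to 9.27% were not aligned, 28.8% to 37.0% were not aligned uniquely, 1.38% to 3.05% were ambiguous and 2.29% to 3.29% had no feature. Symbols and coordinates came from the GENCODE annotation of GRCm38, which held 51719 of the gene IDs. The 193 others held 0.00517% of counts and kept their IDs. Gene totals ran from 16.0 to 18.9 M counts (M, mega) per library. Intervals and floors cover counting error only. The floor is 3 counts over a group, which corresponds to 0.0422 CPM in controls and 0.0381 in asymptomatic livers.

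Counts were filtered with filterByExpr, which left 14638 genes, and scaled by TMM. The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, R 4.3.3), two-sided, in 1 fit of the 14 libraries with a mean per group. P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 3 comparisons were AIH against control, asymptomatic against control and AIH against asymptomatic. CPM are TMM-scaled, and standard errors of log2 fold changes were derived from the F statistic.

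Before the data were examined, 41 gene lists of 718 symbols were fixed for pathways and cell types of liver and blood. Of these symbols 716 matched and 642 were tested. Lists with at least 5 tested members (39) were tested with camera in limma 3.58.1 on voom values with a preset correlation of 0.01. P-values were adjusted over the lists. Camera with an estimated correlation and fry were run beside it. The natural killer cell and pancreas lists had too few tested members and were left out. A rise of the CD8 Tc1 effector list was therefore not set beside a list of natural killer cell genes. The named genes follow a rule also fixed before the data were examined. It took Tet2, Ifng, Tnf, Cd8a, Cd4 and Cyp1a1. It added the 8 largest rises and 8 largest falls among called genes with a mean CPM of at least 1 and no overlap between groups, leaving out gene models and receptor variable segments. It further added up to 3 members with the smallest p of each called list. Where no gene was called, it took the 4 genes with the smallest p. The rule gave more list members than are named here. Which of them are given was settled after their values had been seen. A gene that the rule took is not reported here.

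The other planned settings were RLE factors, library totals alone, removal of the 20 most abundant genes, 2 other count filters, DESeq2 1.42.0, limma-voom with quality weights, a robust spread, only the 2 groups compared, sex as a term, and each library left out in turn. Sex is not in the labels. It was read from Xist and 4 Y-linked genes, and used only as a covariate or to compare groups within a sex. Contrasts within a sex, the share of unaligned reads, and the ratio of Dbp to Arntl (a readout of time of day) were added after the data were seen. Where 1 animal stood on a side, its spread was assumed to be that of the other groups.

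The pipeline was tested on simulated counts at the control means with 200 genes changed. For AIH against control (13826 simulated genes tested), 12 of 48 genes changed 2-fold were called, 39 of 48 changed 4-fold, and 4 of 13633 unchanged genes. For asymptomatic against control (13838 tested), 14 of 47 changed 2-fold were called and 44 of 49 changed 4-fold. For AIH against asymptomatic (13853 tested), these were 20 of 50 and 42 of 47. No unchanged list was called in any of the 3 simulations, where genes varied independently of each other. Figures were drawn with matplotlib 3.10.9.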

Results

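Liver RNA was profiled in mice in which Tet2, an enzyme that oxidizes methylated cytosine in DNA, can be deleted in blood cells by Vav-cre. Part of the deleted animals had developed hepatitis by 20 weeks and part had no symptoms. The 14 libraries came from 4 healthy littermate controls, 5 asymptomatic and 5 AIH mice. Gene totals averaged 18.2 ± 0.538 M counts (M, mega) in controls (SD, n = 4), 16.8 ± 0.798 M in asymptomatic livers (SD, n = 5) and 17.8 ± 0.325 M in AIH livers (SD, n = 5). Xist and Y-linked counts gave 2 females and 2 males among controls, 5 males among asymptomatic mice, and 4 females and 1 male among AIH mice. Group and sex were therefore entangled. Libraries of 1 group correlated at r = 0.899 to 0.986 across genes, and no pair agreed within sampling noise. Asymptomatic 2 was closer to control 4 (r = 0.983, chi-square per gene 29.8) than to its own group (chi-square per gene 117 to 163). The first principal component held 46.4% of the variance and placed the AIH livers apart from the others, with the male AIH 4 nearest to them.

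**Figure D1:**
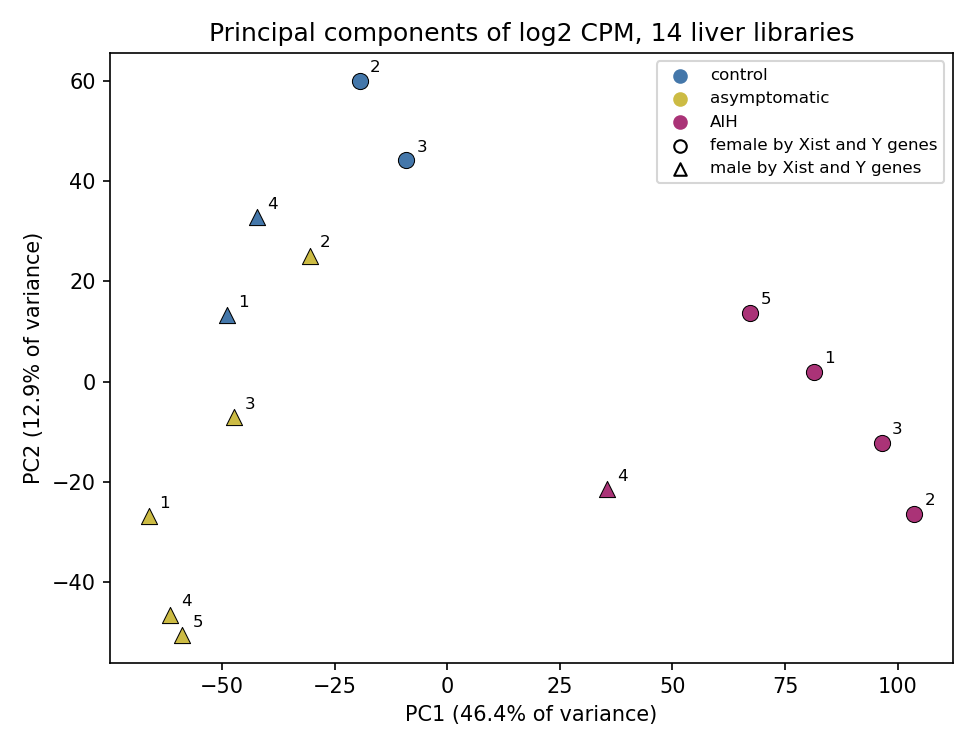
First and second principal components of log2 CPM for the 14 libraries, by group (colour) and sex (symbol), numbered by replicate. The 5 AIH libraries lie at PC1 values of 35.4 to 103.7, above all control and asymptomatic libraries.

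Tet2 (ENSMUSG00000040943, GRCm38 chromosome 3, 133463679 to 133545139, minus strand) averaged 10.7 ± 1.54 CPM in controls (SD, n = 4), 6.82 ± 1.83 in asymptomatic livers and 10.5 ± 3.98 in AIH livers (SD, n = 5 each). Its log2 fold change was -0.65 ± 0.27 in asymptomatic against control (adjusted p = 0.435), -0.03 ± 0.27 in AIH against control (adjusted p = 0.945) and 0.62 ± 0.25 in AIH against asymptomatic (adjusted p = 0.0794), none past the threshold. Blood cells are a minority of liver RNA and the counts cover the whole gene, so this is a weak check of the labels.

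AIH livers were first compared with healthy control livers, to describe the hepatitis. They held more transcripts of myeloid, T and B cells, of dividing cells and of matrix. Transcripts of most fatty acid oxidation genes and of some bile acid genes were fewer. Camera called these lists with the preset correlation, and none passed with an estimated correlation. Of 14638 genes, 3174 changed, with 2284 higher and 890 lower. Among them, 1882 rose and 204 fell by over 2-fold. Groups did not overlap in 19.8% of tested genes, against 1.59% by chance. With library totals as the only scaling, which moves the median log2 fold change of all genes from -0.013 to 0.14, 89.8% of the calls were higher, against 72.0% with TMM.

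The neutrophil and granulocyte precursor list, called granulocyte or granulocyte precursor below, holds genes of mature neutrophils and of granule proteins. It had the largest median of the 39 lists over all libraries. In that list 15 of 16 members rose, with quartiles of 4.43 and 8.77 on the log2 scale (camera adjusted p = 1.27e-05; adjusted p = 0.338 with an estimated correlation). Mpo, the myeloperoxidase of neutrophil granules (chromosome 11, 87793581 to 87804413), averaged 33.3 ± 41.6 CPM in AIH (SD, n = 5) and had 1 count in all 4 controls together, a pooled ratio of 2263 (95% counting interval 406 to 89422). AIH 3 held 105.1 CPM of Mpo, the other AIH libraries averaged 15.4, and without AIH 3 the ratio was 1133. Ctsg, another granule protease, had no count in controls and was at least 139-fold higher, or 68.7-fold without AIH 3. Camp was higher by a pooled ratio of 978 (interval 270 to 8077), or 649 without AIH 2. Ngp and Ltf, both granule proteins, rose by 9.04 ± 1.34 and 8.68 ± 1.19 on the log2 scale. S100a8 rose by 7.87 ± 1.16. Prg2, an eosinophil granule protein, averaged 202 ± 429 CPM, and AIH 3 alone held 969.7. AIH 4 had the lowest Mpo (1.06 CPM) of the AIH group. Erythroid genes moved with them, with 11 of 13 higher (camera adjusted p = 0.00266; adjusted p = 0.441 with an estimated correlation). Slc4a1, the red cell anion exchanger, rose by 5.88 ± 1.22, and with sex in the fit that call ended (4.84, adjusted p = 0.0628). The erythroid list was not called within males (median -0.46, adjusted p = 0.668).

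Lymphocyte genes also rose. In the T cell core list 17 of 18 members rose (median 3.02, camera adjusted p = 1.56e-07; adjusted p = 0.282 with an estimated correlation), among them Cd2 (4.63 ± 0.65) and Cd3g (3.49 ± 0.62). In the CD8 Tc1 effector list 14 of 18 rose (median 2.39, camera adjusted p = 2.39e-08; adjusted p = 0.153 with an estimated correlation), including Ccl5 (3.32 ± 0.49) and Nkg7 (3.53 ± 0.53). Cd8a, the CD8 coreceptor, averaged 2.45 ± 1.09 CPM against 0.336 ± 0.143 in controls (adjusted p = 0.00102). Cd4 rose from 0.990 ± 0.229 to 8.81 ± 8.46 CPM (adjusted p = 0.00374), and Tnf rose by 2.41 ± 0.58 on the log2 scale (adjusted p = 0.00861). Cd4 ran from 1.26 CPM in AIH 5 to 22.0 in AIH 4, and the highest control held 1.17. Ifng was too low to test, with 3 counts over the 4 control libraries, 4 over the asymptomatic and 10 over the AIH libraries. In the checkpoint and costimulation list 12 of 14 rose (median 3.95, camera adjusted p = 1.09e-05; adjusted p = 0.187 with an estimated correlation). Tigit, an inhibitory receptor of T and NK cells, was at least 100.2-fold higher, or 61.9-fold without AIH 1. In the B and plasma cell list 22 of 25 rose (median 4.58, camera adjusted p = 6.41e-08; adjusted p = 0.322 with an estimated correlation). Cd79b, part of the B cell receptor complex, rose by 4.45 ± 0.72. Fcrl5 was higher by a pooled ratio of 587 (interval 162 to 4855). Of 26 tested receptor variable segments, 19 rose and 0 fell.

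All 22 monocyte and macrophage genes rose (median 2.88, camera adjusted p = 3.62e-15; adjusted p = 0.153 with an estimated correlation), with Ccr2, the receptor of recruited monocytes, at 18.4 ± 6.27 against 2.17 ± 0.503 CPM, and Ctss at 343 ± 168 against 56.9 ± 10.1 CPM. In the Kupffer cell list 7 of 10 rose (camera adjusted p = 0.000296; adjusted p = 0.308 with an estimated correlation), and the scavenger receptor Marco rose by 3.85 ± 0.57. All 10 class II presentation genes rose (median 2.46, camera adjusted p = 6.89e-07; adjusted p = 0.187 with an estimated correlation), with Cd74 at 2.41 ± 0.41 and H2-Aa at 2.45 ± 0.44. In the interferon gamma list 12 of 24 rose (median 1.39, camera adjusted p = 1.27e-05; adjusted p = 0.338 with an estimated correlation), among them Irf8 (2.47 ± 0.23). Proliferation genes rose in 22 of 23 cases (median 3.53, camera adjusted p = 1.39e-21; adjusted p = 0.146 with an estimated correlation). Top2a averaged 30.2 ± 5.73 against 2.09 ± 0.402 CPM, and Ccna2 15.9 ± 6.45 against 1.05 ± 0.447 CPM. Stellate cell and matrix genes rose in 16 of 21 cases (median 1.69, camera adjusted p = 4.29e-09; adjusted p = 0.187 with an estimated correlation), with Vim at 2.48 ± 0.26 and Col3a1, a fibrillar collagen, at 2.97 ± 0.42. In the acute phase list 9 of 25 rose (camera adjusted p = 0.000129; adjusted p = 0.385 with an estimated correlation), Orm1 by 2.15 ± 0.41, and within males that list was not called (median 0.31, adjusted p = 0.263). The sinusoidal endothelium list was not called (median -0.034, adjusted p = 0.432; its mean has the opposite sign).

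In the list of fatty acid oxidation and targets of PPARa 16 of 22 members fell (median -1.31, camera adjusted p = 7.05e-09; adjusted p = 0.273 with an estimated correlation). Ehhadh, the peroxisomal bifunctional enzyme, fell from 2111 ± 1883 to 238 ± 114 CPM (adjusted p = 0.0237). That call ended without control 2 (adjusted p = 0.0601), control 4 (0.0641), AIH 1 (0.0537) or AIH 2 (0.0585), and within females (adjusted p = 0.0784). The log2 fold change was -2.77, -2.715, -3.05 and -2.91 in these leave-out fits. Ppara, the receptor that controls these genes, fell from 203 ± 34.9 to 71.5 ± 31.0 CPM. Cpt2 fell by 1.33 ± 0.28, Acaa1b by 2.42 ± 0.57 and Vnn1 by 2.98 ± 0.71 on the log2 scale. AIH 4 held 621.5 CPM of Acaa1b, and the other AIH libraries averaged 138. Bile acid genes fell in 8 of 19 cases (median -0.68, camera adjusted p = 4.57e-06; adjusted p = 0.187 with an estimated correlation), including the uptake carrier Slco1b2 (863 ± 222 against 1722 ± 237 CPM) and the conjugating enzyme Baat (210 ± 32.8 against 336 ± 26.6 CPM). Cyp2e1, a pericentral cytochrome, fell from 8601 ± 412 to 4568 ± 462 CPM. Other genes that fell included Pnldc1 (-3.45 ± 0.84), the water channel Aqp4 (-3.37 ± 0.64), Asic5 (-2.89 ± 0.62), Mogat1 (-2.82 ± 0.57) and Hhipl2 (-2.22 ± 0.57). Cyp1a1, a target of the aryl hydrocarbon receptor, had a log2 fold change of -0.32 ± 0.48 (adjusted p = 0.686).

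**Figure D2:**
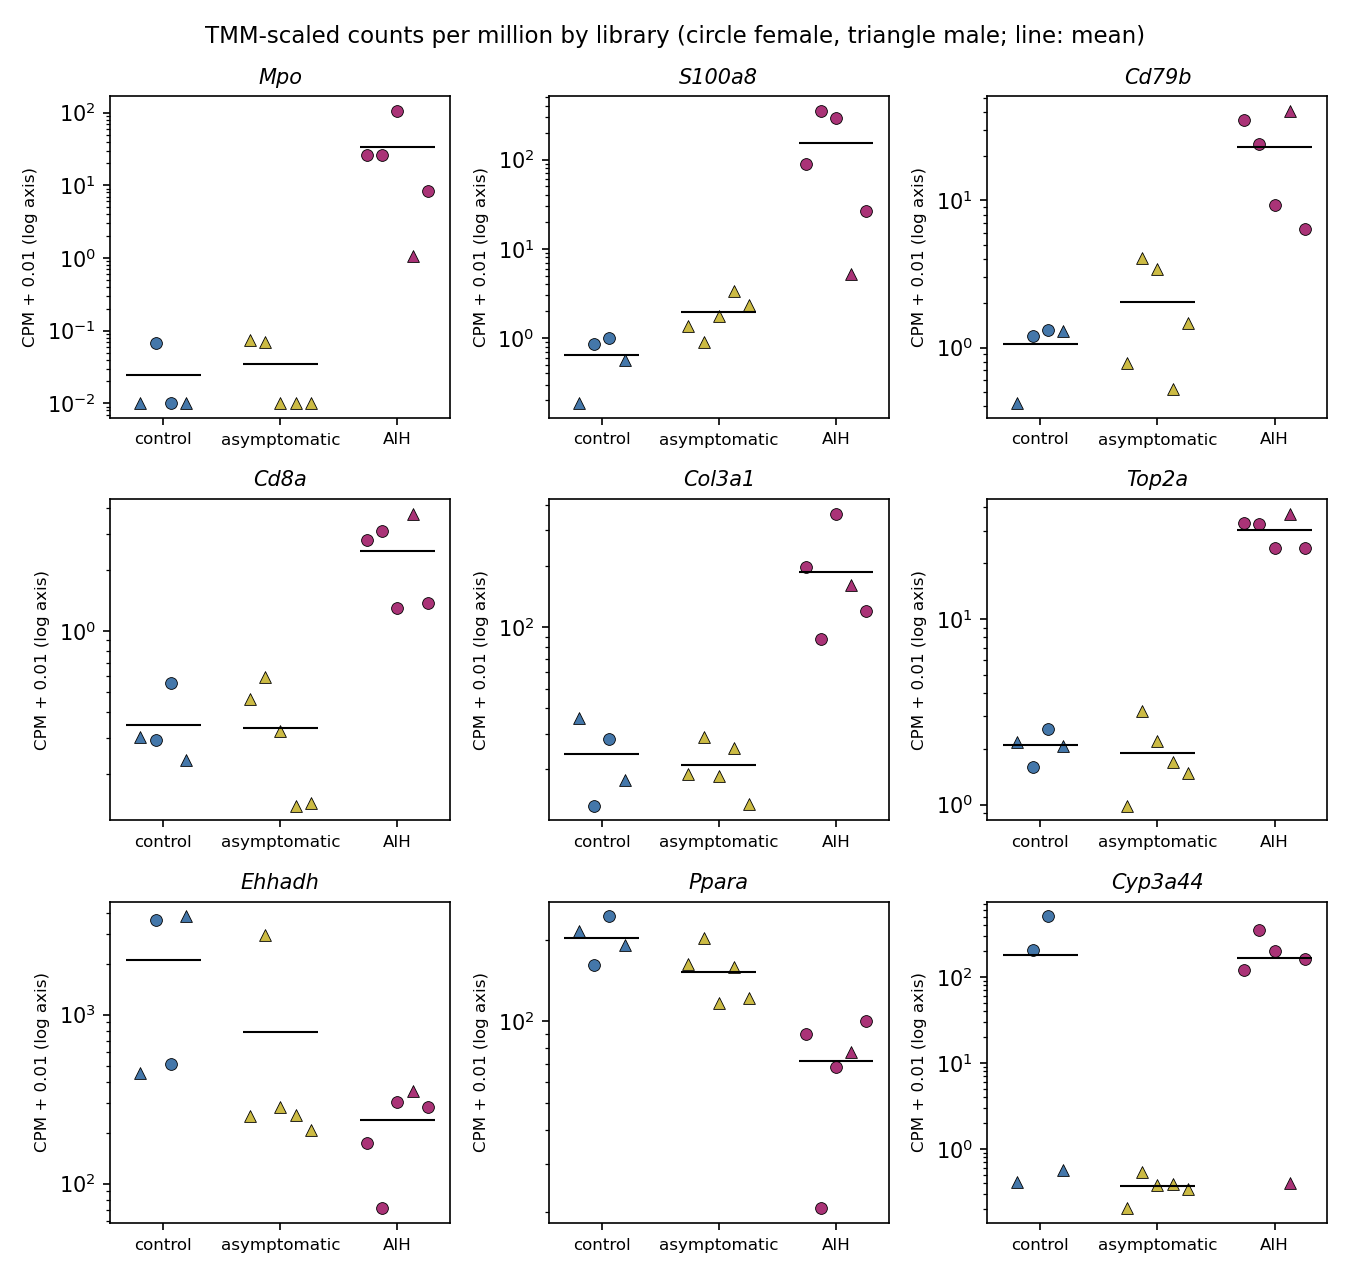
TMM-scaled CPM plus 0.01 on a log axis for 9 genes in each library, by group and sex, with lines at the group means. In the Cd8a, Col3a1 and Top2a panels every AIH library lies above every other library, while Cyp3a44 parts females from males in each group that holds both.

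Called over the list alone, members higher and lower numbered 25 and 0 for B and plasma cell, 17 and 0 for CD8 Tc1 effector, 19 and 0 for stellate cell and matrix, and 0 and 19 for fatty acid oxidation (adjusted over the list alone). Members higher numbered 14 for interferon gamma, 10 for acute phase, 15 for granulocyte precursor, 12 for checkpoint and costimulation and 17 for T cell core, and 8 bile acid genes were lower (adjusted over the list alone). Within females (4 AIH, 2 control) 1746 genes changed, 1379 higher and 367 lower, of which 1636 were among the 3174. In males (1 AIH, 2 controls) 447 were called, 442 of them higher, with the lone AIH male assumed to vary like the others. All 16 granulocyte genes rose within females (median 7.51), while none was called in the single male (median 2.81).

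**Figure D3:**
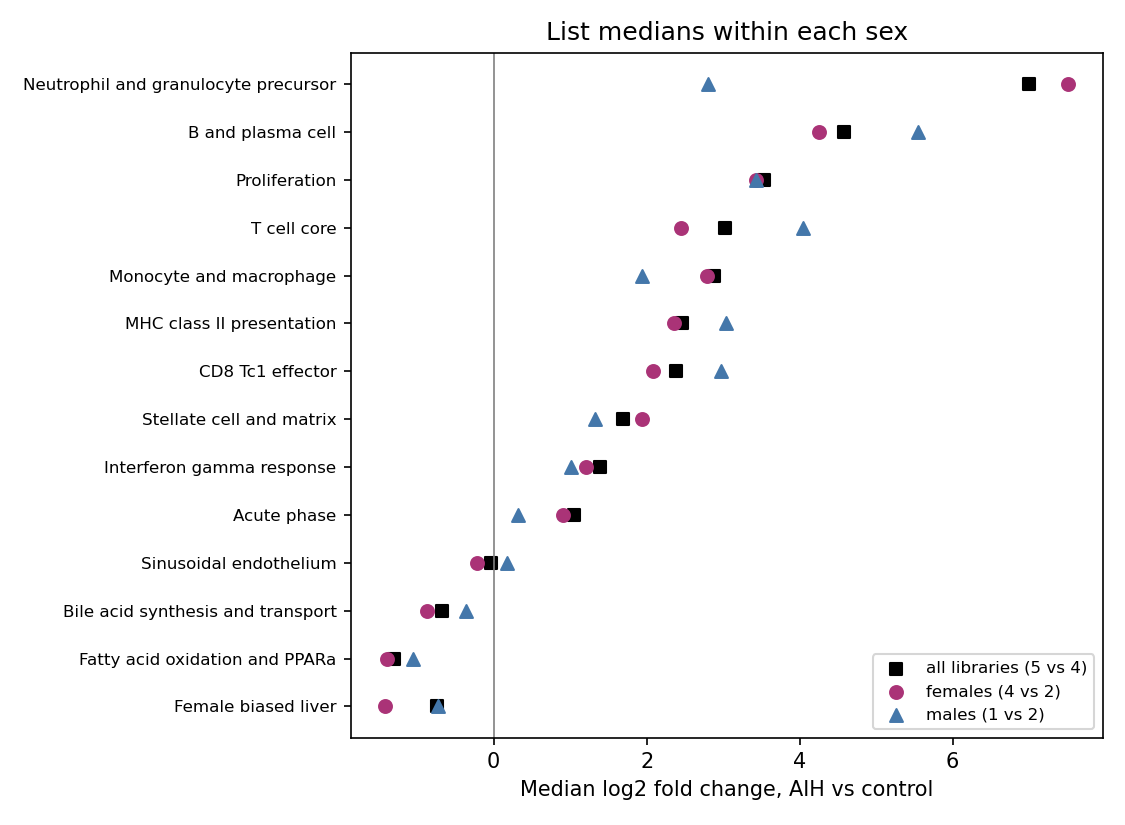
Median log2 fold change of 14 lists in AIH against control, over all libraries, within females and within males (1 AIH animal). The granulocyte median is 7.51 in females and 2.81 in males, while the B and plasma cell median is 4.25 in females and 5.55 in males.

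Asymptomatic livers were compared with controls to ask what Tet2 deletion in blood cells does without overt hepatitis. No gene passed the threshold in edgeR's test, and 1542 of 14638 had an unadjusted p under 0.05. DESeq2 called 118 genes and limma-voom with quality weights 1299. The smallest adjusted p was 0.0977, for Acsm2, which averaged 1.91 ± 0.904 against 0.0979 ± 0.0524 CPM. Meg3 (4.67 ± 0.88), Abcc4 (-1.79 ± 0.36) and Cela1 (2.15 ± 0.45) followed, each at an adjusted p of 0.308. Without asymptomatic 2, the 1 asymptomatic library with few unaligned reads, 13 genes were called, among them Acsm2 (adjusted p = 0.0123), Meg3 (0.0123) and Cela1 (0.0323). Cd4 averaged 1.67 ± 0.231 against 0.990 ± 0.229 CPM (adjusted p = 0.692), Cd8a 0.324 ± 0.201 against 0.336 ± 0.143 (adjusted p = 0.982) and Tnf 0.272 ± 0.200 against 0.183 ± 0.0970 (adjusted p = 0.791). Cyp1a1 had a log2 fold change of 0.04 ± 0.48.

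Of the 39 lists 6 were called by camera, though none of their members passed alone over all genes. The male biased list was higher (median 1.73, camera adjusted p = 3.26e-10; adjusted p = 0.928 with an estimated correlation), with Cyp7b1 at 671 ± 385 against 92.8 ± 73.6 CPM, Ugt2b38 at 4.89 ± 1.70 and Serpina1e at 2.78 ± 1.13 on the log2 scale. With the unaligned share in the fit Cyp7b1 (-0.24 ± 0.65) and Ugt2b38 (-1.03 ± 1.18) changed sign. The female biased list was lower (median -8.07, camera adjusted p = 0.00116; adjusted p = 0.998 with an estimated correlation), and all 16 members fell when adjusted over the list alone. Cyp3a16 averaged 0.913 ± 0.418 against 255 ± 302 CPM and Cyp3a44 0.364 ± 0.120 against 179 ± 240 CPM. Cyp3a41a had 1 count in the asymptomatic group, a pooled ratio of 4095 in favour of controls (interval 735 to 161800), or 2610 without control 3. All asymptomatic mice were male. With sex in the fit the female biased list was not called (median -0.17, adjusted p = 0.310), while the male biased list still was (median 0.80, camera adjusted p = 0.00808), as within males (median 0.90, camera adjusted p = 0.000822). The fatty acid oxidation list was lower (median -0.66, camera adjusted p = 1.7e-07; adjusted p = 0.928 with an estimated correlation), with Vnn1 at -1.80 ± 0.68, Acadl at -0.62 ± 0.25 and Acadm at -0.74 ± 0.32, none past the threshold. Within libraries with few unaligned reads Acadl (0.11 ± 0.31) and Acadm (0.16 ± 0.42) changed sign. Asymptomatic 2 is the only asymptomatic library in that contrast. Within males the median of the list was -0.63 (camera adjusted p = 1.17e-06). The log2 ratio of Dbp to Arntl was 7.56, -4.51, 6.81 and -2.86 in controls 1, 2, 3 and 4. It was 1.41 to 6.08 in asymptomatic livers, so harvest time stays open for this list. Complement and coagulation was higher by a small median of 0.12 (camera adjusted p = 0.00465). Camera with an estimated correlation gave an adjusted p of 0.928. In that list C8b was at 568 ± 247 against 142 ± 94.5 CPM and C9 at 1.45 ± 0.38. Cholesterol synthesis was called higher with a median of only 0.092 (camera adjusted p = 0.0186). Camera with an estimated correlation gave an adjusted p of 0.998. Idi1 was at 0.73 ± 0.62, Sqle at 0.56 ± 0.51 and Srebf2, a regulator of this pathway, at -0.35 ± 0.20. All 3 changed sign within libraries with few unaligned reads (-0.96, -0.46 and 0.012), where asymptomatic 2 alone stands for its group. Immediate early genes were lower (median -0.56, camera adjusted p = 0.008; adjusted p = 0.928 with an estimated correlation), with Myc at -0.78 ± 0.21 and Fos at -1.35 ± 0.50. That list was not called with sex in the fit (median -0.085, adjusted p = 0.281) or within males (median -0.20, adjusted p = 0.403), and its call held in 7 of the 9 fits that each left out a library. The cholesterol call held in 6 of 9 such fits (highest camera adjusted p = 0.866). It also held with sex in the fit (camera adjusted p = 0.00227) and within males (camera adjusted p = 3.31e-05). Over all libraries no immune list was called, among them monocyte and macrophage (median 0.0068, adjusted p = 0.988) and T cell core (median -0.11, adjusted p = 0.993). Once sex was in the fit, where again no member passed alone, camera called monocyte and macrophage (median 0.46, adjusted p = 0.00227), Kupffer cell (0.67, 0.00208), granulocyte precursor (2.29, 0.00314), erythroid (1.65, 0.000286), progenitor, mast cell and megakaryocyte (0.12, 0.0107), type I interferon (0.48, 0.00691) and acute phase (0.79, adjusted p = 6.99e-09) higher. Within males it called Kupffer cell (median 0.52, adjusted p = 0.0120), type I interferon (0.49, 0.0324) and acute phase (0.75, adjusted p = 1.17e-06) higher, but not monocyte and macrophage (adjusted p = 0.0989), granulocyte precursor (0.901), erythroid (0.188) or progenitor, mast cell and megakaryocyte genes (0.580). With only males among asymptomatic mice, the sex effect came from controls and from the lone AIH male against the other AIH mice. Traits of that animal, such as its low Mpo, may therefore enter the medians with sex in the fit. For lists called there but not within males, a rise hidden by sex cannot be told apart from such traits. None of the 39 lists passed with an estimated correlation with sex in the fit (lowest adjusted p = 0.6125) or within males (lowest 0.6262). Fry called 0 of the 39 lists in this comparison. The unaligned share was 7.67% ± 1.63 in asymptomatic and 4.67% ± 0.341 in control libraries (exact permutation test, two-sided, p = 0.0159, adjusted over 12 tests 0.0476), and the share not aligned uniquely was higher by 4.69 percentage points (same test, exact p = 0.0159, adjusted 0.0476).

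AIH livers were last compared with asymptomatic livers of the same genotype, to ask what goes with disease. Again many immune, proliferation and matrix genes were higher, though no list passed with an estimated correlation. Of 14638 genes 4355 changed, 2796 higher and 1559 lower. Groups did not overlap in 16.9% of tested genes, against 0.794% by chance. With sex in the fit 1372 were called, 1320 of them among the 4355, and with the unaligned share 562. Most lower calls were lost there, with 150 left (1222 higher) with sex and 18 (544 higher) with the unaligned share. All asymptomatic mice were male, so the sex effect in that fit came from the controls and from AIH 4 against the other AIH mice. Only AIH 4 among the AIH libraries had over 6% unaligned reads, and only asymptomatic 2 among the asymptomatic had less. Lost calls therefore do not tell sex or unaligned share apart from traits of these libraries. Within males, 1 AIH animal against 5, 785 genes were higher and 27 lower. With library totals alone 88.9% of calls were higher, against 64.2%, and the median of all genes moved from -0.032 to 0.17.

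Proliferation genes rose in 22 of 23 cases (median 3.29, camera adjusted p = 2.63e-18; adjusted p = 0.131 with an estimated correlation), with Top2a at 3.98 ± 0.28 and 4.14 with sex in the fit, and Ccna2 at 3.79 ± 0.32. All 22 monocyte and macrophage genes rose (camera adjusted p = 6.74e-14; adjusted p = 0.131 with an estimated correlation), with Ccr2 at 3.07 ± 0.29 and Ctss at 2.58 ± 0.27. Matrix genes rose in 17 of 21 cases (camera adjusted p = 4.47e-10; adjusted p = 0.149 with an estimated correlation), Vim by 2.70 ± 0.24. CD8 Tc1 genes rose in 17 of 18 cases (camera adjusted p = 5.7e-09; adjusted p = 0.131 with an estimated correlation), with Ccl5 at 4.09 ± 0.47 and Nkg7 at 3.81 ± 0.49. T cell core genes rose in 17 of 18 cases (camera adjusted p = 4.94e-07; adjusted p = 0.346 with an estimated correlation), Cd3g by 4.15 ± 0.59. B and plasma cell genes rose in 21 of 25 cases (camera adjusted p = 4.94e-07; adjusted p = 0.375 with an estimated correlation), with Ighg2c at 57.1 ± 49.5 against 1.15 ± 1.63 CPM and Cd79b at 3.49 ± 0.62. Asymptomatic 2 held 4.06 CPM of Ighg2c, and the other asymptomatic libraries averaged 0.421. The checkpoint receptors Pdcd1 (6.74 ± 1.06) and Havcr2 (4.04 ± 0.47) rose. Cd8a rose by 2.88 ± 0.46, Cd4 by 2.39 ± 0.58 and Tnf by 1.87 ± 0.52, of which Tnf was not called with sex in the fit (adjusted p = 0.144). Class II genes rose in 10 of 10 cases (camera adjusted p = 1.03e-06; adjusted p = 0.216 with an estimated correlation), Cd74 by 2.49 ± 0.38, and interferon gamma genes in 18 of 24 (camera adjusted p = 2.28e-06; adjusted p = 0.346 with an estimated correlation), Irf8 by 2.30 ± 0.21. Immediate early genes rose in 13 of 15 cases (camera adjusted p = 8.91e-07; adjusted p = 0.131 with an estimated correlation), with Fos at 3.71 ± 0.49 and Myc at 2.13 ± 0.20. Marco rose by 3.57 ± 0.51.

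Granulocyte genes rose in 15 of 16 cases (median 6.18, camera adjusted p = 1.89e-05; adjusted p = 0.375 with an estimated correlation). With sex in the fit the median was 3.51 and 3 members were called (camera adjusted p = 0.00229; adjusted p = 0.509 with an estimated correlation). Over all libraries erythroid genes rose in 8 of 13 cases (median 3.40, camera adjusted p = 0.0424; adjusted p = 0.594 with an estimated correlation). That erythroid call held in 3 of the 10 fits that each left out a library. Mpo had 2 counts in the asymptomatic group, a pooled ratio of 1255 (interval 347 to 10370). Camp had 3 counts there, a ratio of 723 (interval 247 to 3508). Ctsg was at least 154-fold, the mast cell and basophil protease Prss34 at least 65.9-fold and Apol8 at least 60.4-fold higher. Without AIH 3 the Mpo ratio was 628 and Ctsg at least 76.2-fold higher, and without AIH 2 the Camp ratio was 480 and Apol8 at least 23.4-fold higher. Prg2 rose by 10.55 ± 1.93 (6.21 ± 0.64 without AIH 3), Ngp by 9.73 ± 1.28 and Ltf by 9.72 ± 1.19, and with sex in the fit the calls of Prg2, Ctsg, Camp, Prss34 and Apol8 ended (adjusted p = 0.132, 0.598, 0.157, 0.388 and 0.588). Genes that fell with no overlap between the groups included Asic5 (-4.38 ± 0.63), Aqp4 (-3.31 ± 0.63), Tsku (-2.83 ± 0.55), Ugt1a10 (-2.77 ± 0.81), Omd (-2.73 ± 0.85), Tmem28 (-2.58 ± 0.82), Snhg11 (-2.45 ± 0.65) and Mcm10 (-2.24 ± 0.53). The Omd call ended without AIH 1, 2 or 5 (adjusted p = 0.0551, 0.0551 and 0.0522), and the Tmem28 call without asymptomatic 1 or 3 (0.0564 and 0.0547) or AIH 1, 2, 3 or 5 (0.0636, 0.0653, 0.0594 and 0.0618). Of these Asic5, Tsku and Ugt1a10 were also called with sex in the fit (adjusted p = 0.00161, 0.0452 and 0.00285).

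Genes with sex-biased liver expression differed between these groups of unlike sex. The female biased list was higher (15 of 16 rose, median 7.58, camera adjusted p = 0.0424; adjusted p = 0.617 with an estimated correlation), with Cyp3a44 at 8.81 ± 1.94 and Sult2a1 at a log2 fold change of 8.93. With sex in the fit these were -0.18 and -1.73, no member rose, and the list was lower (median -1.01, camera adjusted p = 0.0405; adjusted p = 0.313 with an estimated correlation). The pooled call held in 2 of the 10 fits that each left out a library. The male biased list was lower (4 of 13 fell, camera adjusted p = 7.24e-06; adjusted p = 0.346 with an estimated correlation), with Cyp7b1 at -3.04 ± 0.94 and Cyp2u1 at -3.06 ± 0.88. AIH 4, the AIH male, held 321.2 CPM of Cyp7b1 and 18.52 of Cyp2u1. The other AIH libraries averaged 21.33 and 1.231 CPM. The Cyp7b1 call ended without asymptomatic 4 (adjusted p = 0.0526) or AIH 2, 3 or 5 (0.0591, 0.0526 and 0.0560). The male biased list was not called with sex in the fit (median -0.083, adjusted p = 0.494). Fatty acid oxidation genes fell in 4 of 22 cases and rose in 1 (median -0.73, camera adjusted p = 0.00344; adjusted p = 0.525 with an estimated correlation; held in 9 of 10 leave-out fits, highest adjusted p = 0.0966), with Fabp1 at -1.14 ± 0.22 and Ppara at -1.09 ± 0.32. Bile acid genes fell in 6 of 19 cases and rose in 1 (camera adjusted p = 0.000181; adjusted p = 0.313 with an estimated correlation). Baat was lower by 0.69 ± 0.14 on the log2 scale. Within males neither the fatty acid oxidation (median -0.51, adjusted p = 0.151) nor the bile acid list (median -0.19, adjusted p = 0.153) was called. Acute phase genes rose in 13 of 25 cases (camera adjusted p = 0.00448; adjusted p = 0.525 with an estimated correlation), Orm2 from 9.73 ± 4.93 to 463 ± 465 CPM and Apcs, serum amyloid P, by 2.96 ± 0.63 on the log2 scale. Both changed sign within males (Orm2 -0.57, Apcs -0.14) and within libraries with many unaligned reads (-0.77 and -0.12). AIH 4 is the only AIH library in each of these contrasts, so they are not separate checks. With sex in the fit the acute phase list was not called (median -0.15, adjusted p = 0.642), nor within males (median -0.23, adjusted p = 0.0997). Cyp1a1 had a log2 fold change of -0.36 ± 0.46. Members higher numbered 18 for CD8 Tc1 effector, 23 for B and plasma cell, 19 for stellate cell and matrix, 19 for interferon gamma, 16 for granulocyte precursor, 15 for female biased and 13 for acute phase, and members lower numbered 2 for fatty acid oxidation, 7 for bile acid and 4 for male biased (adjusted over the list alone).

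**Figure D4:**
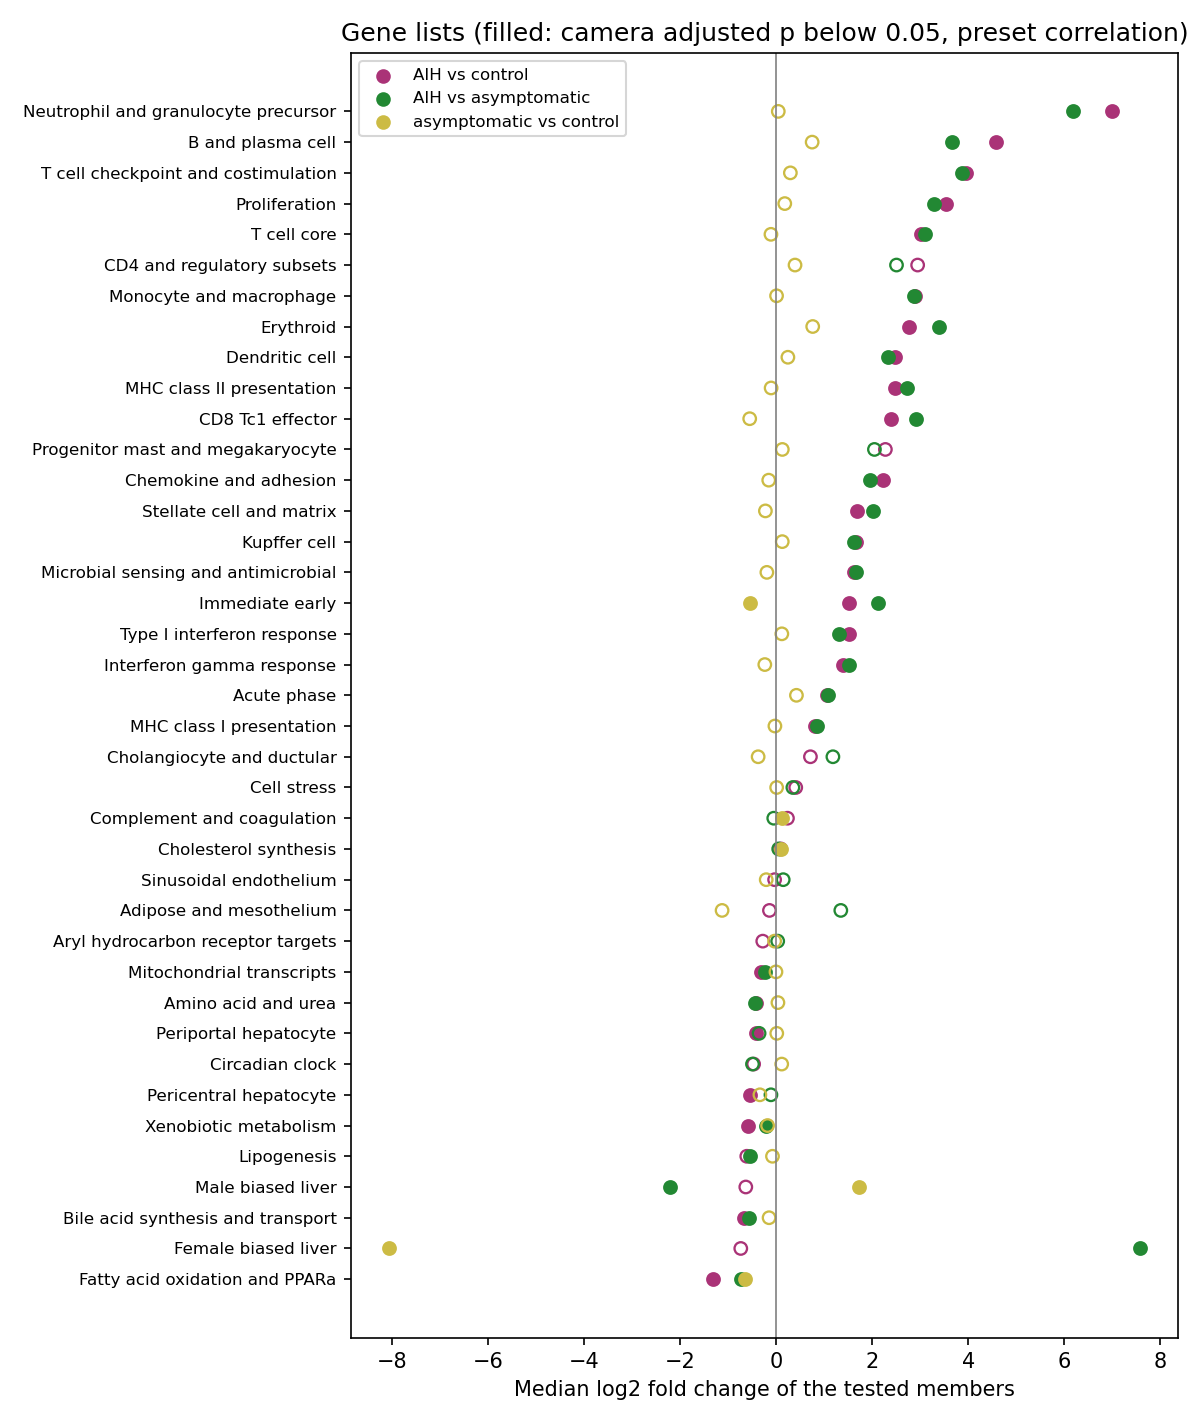
Median log2 fold change of the tested members of each of 39 lists in the 3 comparisons. Filled points passed camera with the preset correlation, and no list passed with an estimated correlation. The granulocyte precursor median is 6.18 in AIH against asymptomatic and 0.043 in asymptomatic against control.

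The comparisons of each cre-positive group with control share the 4 control libraries. By edgeR no gene was called in both, where asymptomatic against control had 0 calls (1542 at an unadjusted p under 0.05, with 118 calls by DESeq2 and 1299 by limma-voom). Fold changes correlated across genes, which are not independent replicates, at 0.165 (0.558 in simulations) with a covariance of 0.125, against a mean covariance of 0.100 in 20 simulations of unchanged groups. With the controls split into separate pairs the covariance ran from -0.188 to 0.146.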

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

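All tests in this part were chosen after the results were seen. Among 204 sets of values in a group, 23 had a library far from the others, against 10.2 by chance at 1 in 20. The 10.2 holds for normally distributed values. CPM are skewed, and a set with only 1 value above 0 is always flagged. The excess is therefore no evidence of unusual libraries. AIH 4, the male AIH liver, stood apart 6 times. It held more Acaa1b (621.5 CPM against 138 on average in the other AIH libraries), Pnldc1 (0.6715), Tmem28 (2.24), Cyp7b1 (321.2) and Cyp2u1 (18.5), and 6.54% unaligned reads against 3.57%. AIH 3 held Mpo at 105.1 and Prg2 at 969.7 CPM. AIH 2 held Ccl5 at 31.15, Nkg7 at 15.9 and Apol8 at 7.92 CPM. Asymptomatic 2 stood apart 6 times, with Acadl at 402.6, Acadm at 673, C9 at 391.6, Ccr2 at 3.29, Ighg2c at 4.06 and Pdcd1 at 0.235 CPM. Control 2 was lowest in Ccr2 (1.41) and the only control with an Mpo count (0.0565 CPM). Control 1 was lowest in Cd79b (0.409) and highest in Ugt2b38 (5.495). Control 4 had Camp at 0.112 and asymptomatic 5 had Cyp3a41a at 0.0665 CPM, where the rest had 0. Outside the gene counts, the unaligned share averaged 7.67% in asymptomatic libraries against 4.67% in controls. The edgeR test of whether AIH changed genes differently in females and males had AIH 4 as the only AIH male. It could not decide whether the sexes responded alike, and no other tool was run on it.

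Other splits of the libraries were fitted. For AIH against control 1 of 100 splits, the real one, gave 3174 genes, and the highest other gave 78. Chance alone is thus unlikely for that count, at 1 in 100 splits. For AIH against asymptomatic 1 of 100 gave 4355, and the highest other gave 1127. Chance alone is again unlikely, though that grouping goes with sex and with the unaligned share. That other split set asymptomatic 1, 2, 4 and 5 and AIH 4, all male, against the rest. Setting asymptomatic 1, 3, 4 and 5 and AIH 4, the libraries with over 6% unaligned reads, against the rest gave 959. In 2 further splits with 4 asymptomatic mice and AIH 4 in 1 group, of the same sex makeup, 0 genes were called, so sex makeup alone does not decide these counts. For asymptomatic against control the real count was 0 genes, which all 100 splits reach, so that count says nothing about chance. The highest split gave 571 when asymptomatic 1, 3, 4 and 5, the libraries with over 6% unaligned reads, were set against the other 5. That is the real grouping with asymptomatic 2 moved to the controls, so the unaligned share, the genotype and the likeness of asymptomatic 2 to control 4 were not separated by it. Numbers of called lists did not exclude chance. As many were called in 20 of 100 splits for AIH against control (26 lists, highest other 32), 75 for asymptomatic against control (6, highest other 16) and 6 for AIH against asymptomatic (27, highest other 29).

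Neutrophil and granulocyte precursor genes had the largest median of the lists in AIH against control over all libraries. More blood of unchanged makeup left in the tissue would raise globin genes as much, but the 4 globin genes rose by a median of 2.25, against a lower quartile of 4.43 for the list. A lower share of hepatocytes would raise endothelial markers alike, but these had a median of -0.034. Sex composition is argued against by a median of 7.51 within females. Neutrophils, their precursors or other blood-forming cells in the AIH livers, or blood of altered makeup, may be the source and stay open as hypotheses. The list mixes genes of mature neutrophils and of granule proteins, so its median does not tell these apart.

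Female biased genes were higher in AIH than in asymptomatic livers. With sex in the fit the list's median was -1.01 with no member higher (camera adjusted p = 0.0405, lower; adjusted p = 0.313 with an estimated correlation), which is consistent with the unlike sex of these groups. A rise in diseased livers of either sex is argued against by a median of -1.42 within females.

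In the fatty acid oxidation list 16 of 22 members were lower in AIH than in control livers (camera adjusted p = 7.05e-09; adjusted p = 0.273 with an estimated correlation). Dilution by RNA of other cells would lower other hepatocyte lists as much. Amino acid and urea genes had a median of -0.41 and complement and coagulation genes 0.23, or -0.13 together. The fatty acid list had an upper quartile of -1.004, below these medians. That argues against dilution as the whole cause. Camera also called the bile acid (median -0.68, 8 of 19 fell), xenobiotic (-0.59, 5 of 23) and pericentral lists (-0.55, 3 of 16, with 1 higher) lower. None of them passed with an estimated correlation (camera adjusted p = 0.187, 0.216 and 0.409). Dilution as part of the fall therefore stays open. The fall was -1.40 within females, which argues against sex as the whole cause. It was -1.09 with the time of day term in the fit, which argues against a linear effect of that ratio as the whole cause. The log2 ratio of Dbp to Arntl was 7.56, -4.51, 6.81 and -2.86 in controls 1, 2, 3 and 4. It was -1.86 in AIH 4 and 2.62 to 5.74 in the other AIH livers. A linear term cannot model the phase of the day, so harvest time stays open. Food intake and body condition of the sick mice were not measured here and stay open, beside a change in the hepatocytes themselves, as hypotheses.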

How the results depend on the processing

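Contrasts within a sex or an unaligned-read class, the unaligned and time-of-day terms, and the sex term for lists were chosen after the data were seen. Except as stated, causes were not tested. AIH against control stayed within 1.5 times its 3174 genes in every setting but 2, within females (1746) and within males (447), where fewer samples enter. It ran from 2350 to 3425 with a library left out. AIH against asymptomatic gave 1372 genes with sex in the fit, 562 with the unaligned share, 812 within males, 625 within libraries with few and 1007 within libraries with many unaligned reads, and 3317 to 4649 with a library left out. Asymptomatic against control gave 0 genes except in DESeq2 (118), limma-voom with quality weights (1299) and without asymptomatic 2 (13), a range of 0 to 13 with a library left out. With an estimated correlation 0 lists were called in each comparison, from 26, 6 and 27, and 0 with sex in the fit or within a sex. Fry called 24, 0 and 22. For asymptomatic against control, 13 lists were called with sex in the fit and 10 within males. Leaving out a library gave 24 to 30 lists in AIH against control, 5 to 8 in asymptomatic against control and 22 to 28 in AIH against asymptomatic. Genes called in both comparisons with control numbered 28 when AIH was set against controls 1 and 4 and asymptomatic against the others, which splits the controls by sex, 1 of them higher and 1 lower in both, and 0 in the other 5 splits and at an adjusted p below 0.01. Gene totals differed between asymptomatic and control by -1.45 M counts (exact permutation test, adjusted p = 0.0635, not past the threshold), and without the 20 most abundant genes by -1.23 M (adjusted p = 0.0476).

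The Tet2 log2 fold change in AIH against control changed sign with library totals only (0.10) and within libraries with few unaligned reads (0.062), and ran from -0.21 to 0.082 with a library left out. In asymptomatic against control it was -0.72 in limma-voom with quality weights (adjusted p = 0.0487). In AIH against asymptomatic it was 0.81 with library totals only (adjusted p = 0.0253), and 0.44 to 0.75 with a library left out, passing without asymptomatic 2 (adjusted p = 0.0430). Of 47 genes named in that comparison, 18 lost their call and 3 reversed with sex in the fit, and 26 lost it with the unaligned share. Other reversals in AIH against control were Cyp1a1 (0.11) and Slc4a1 (-0.48) within males. In AIH against asymptomatic, Cyp1a1 was 0.15 with sex in the fit, 0.31 within males and 0.38 within libraries with many unaligned reads. Cyp3a44 was -0.18 and Sult2a1 -1.73 with sex in the fit. Sult2a1 was -1.35 within males and -0.69 in the many-unaligned class, Orm2 -0.57 and -0.77, and Apcs -0.14 and -0.12. In asymptomatic against control, where no gene was called, with the unaligned share Cd8a was 0.034, Cd4 -0.10, Cyp1a1 -0.16, Ugt2b38 -1.03, Cyp7b1 -0.24 and Idi1 -0.58. Among libraries with few unaligned reads, asymptomatic 2 was the only asymptomatic library. There Tnf was -0.61, Cd8a 0.79, Acadl 0.11, Acadm 0.16, Idi1 -0.96, Sqle -0.46 and Srebf2 0.012. Within males Cd8a was 0.34, Cyp1a1 -0.20 and Srebf2 0.086. Cyp1a1 was -0.28 with sex in the fit and -0.015 with library totals only. With a library left out Cd8a ran from -0.37 to 0.29 and Cyp1a1 from -0.11 to 0.28.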

Other observations

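Within females, 6 of 16 female biased liver genes fell in AIH against control and none rose (median -1.42, camera adjusted p = 5.93e-07; adjusted p = 0.117 with an estimated correlation), while over all libraries none was called in this list (median -0.74). Further lists moved in AIH against control. Chemokine and adhesion genes rose in 12 of 16 cases (camera adjusted p = 2e-05; adjusted p = 0.153 with an estimated correlation), dendritic cell genes in 10 of 12 (camera adjusted p = 1.07e-05; adjusted p = 0.153 with an estimated correlation) and class I presentation genes in 8 of 15 (camera adjusted p = 5.38e-06; adjusted p = 0.266 with an estimated correlation). Microbial sensing genes rose in 15 of 22 cases and fell in 1 (camera adjusted p = 1.65e-06; adjusted p = 0.187 with an estimated correlation), and type I interferon genes rose in 14 of 21 (camera adjusted p = 3.31e-06; adjusted p = 0.338 with an estimated correlation). Xenobiotic metabolism genes fell in 5 of 23 cases (camera adjusted p = 0.000702; adjusted p = 0.216 with an estimated correlation). Of 7 tested targets of the aryl hydrocarbon receptor 2 rose, and the list was not called (adjusted p = 0.884). Cholesterol synthesis (23 genes, median 0.09) and circadian clock genes (15 genes, median -0.47) had no called member. Immediate early genes rose in 8 of 15 cases (camera adjusted p = 2e-05; adjusted p = 0.187 with an estimated correlation). Amino acid and urea genes fell in 2 of 22 (camera adjusted p = 0.000745; adjusted p = 0.338 with an estimated correlation), mitochondrial transcripts in 1 of 13 (camera adjusted p = 0.0197; adjusted p = 0.451 with an estimated correlation) and pericentral genes in 3 of 16 with 1 higher (camera adjusted p = 0.0280; adjusted p = 0.409 with an estimated correlation). The periportal list was lower by camera (adjusted p = 0.0376; adjusted p = 0.338 with an estimated correlation), though 1 member rose and none fell. The last 3 calls held in 7, 7 and 8 of the 9 fits that each left out a library. Mitochondrial and periportal lists were not called within females (adjusted p = 0.119 and 0.0517) or within males (0.123 and 0.129), and the former not with sex in the fit (0.0829). Of 8 CD4 and regulatory genes 5 rose and of 9 progenitor, mast cell and megakaryocyte genes 5 rose and 1 fell, with neither list called (adjusted p = 0.0912 and 0.0880). Both were called by camera with sex in the fit (camera adjusted p = 0.0142 and 0.00902; adjusted p = 0.129 and 0.271 with an estimated correlation). Within females the progenitor list was called (camera adjusted p = 0.00102; adjusted p = 0.190 with an estimated correlation) and within males the CD4 list (camera adjusted p = 0.00148; adjusted p = 0.0927 with an estimated correlation).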
